A study of Homo sapiens with 6 samples.

How the data were processed

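The series holds RNA sequencing of MDA-MB-231 cells, an established human triple-negative breast cancer line, carrying either an shRNA against CALR or a non-targeting control. Per the labels' protocols, cells were grown in serum-containing medium and collected at subconfluence, total RNA was treated with DNase on the column, and libraries were made from polyadenylated RNA with a kit that keeps the strand. The labels put 3 libraries in the CALR knockdown group and 3 in the control group, and all 6 entered every comparison except those stated to leave a library out. The labels do not state whether the 3 libraries of a group came from separate cultures, infections or shRNA sequences. The p-values therefore measure only the spread between these libraries. Chi-square per tested gene between libraries of a group was 105 to 199 for knockdown pairs and 11.8 to 48.1 for control pairs. Chance sampling of reads from the same library would give far smaller values, which argues against repeat sequencing of it. Whether libraries were prepared separately from the same RNA or culture stays open, so part of the spread may still be technical.

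The deposited count table gives whole numbers of reads per gene for 31582 genes, and the deposited FPKM table gives values rounded to 2 decimals for 31356 genes. Per the submitters' processing notes, FastQC 0.9.5, TopHat2 and the genome build GRCh38 were used; the counting program, its strand setting and the annotation are not given in the sources used here. For the 3237 genes with more than 2000 reads in every library, the ratio of the count to the deposited FPKM value was one constant per gene times one constant per library, with a relative SD of at most 2.5e-04, so both tables describe the same counting. Gene identifiers carry version numbers. Of the 31582, 30871 matched GENCODE release 29 without the version and 27033 with it, and symbols, gene types and identifiers were taken from the deposited table. Coordinates are those of GENCODE 29 on GRCh38, counted from 1. Since strand handling during counting is unknown, reads of overlapping genes cannot be assigned with certainty. Overlaps given with the results are for the same strand only. Genes on the other strand also overlap exon bases, for example 33.2% for MTHFD2, 31.1% for PLAU, 24.4% for VIM, 18.9% for PDIA3 and 18.6% for FDPS.

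The library totals lay between 34639090 and 42425310 counts. Genes were kept with edgeR's filterByExpr at its default settings, which left 16394, and library sizes were scaled with TMM factors. The quasi-likelihood F-test of edgeR 4.0.16 under R 4.3.3 compared CALR knockdown with control, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values use the TMM-scaled library sizes, and log2 CPM values used for per-library differences have a prior count of 2. Single values compared between groups had an exact two-sided permutation test, for which 3 against 3 libraries allow no p below 0.1.

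The design, the alternatives and 21 gene lists were fixed before the data were examined. The lists covered Wnt/beta-catenin target genes, Wnt receptors, ligands and transducers, hypoxia and HIF-1 targets, breast cancer stem cell genes, ER chaperones without CALR, ATF4/CHOP stress genes, MHC class I antigen presentation, calcium handling, mesenchymal and invasion genes, epithelial junctions and keratins, integrins and matrix, S phase, G2/M, interferon-stimulated genes, NF-kB cytokines, cholesterol synthesis, mitochondrially encoded mRNAs and immediate early genes, with luminal breast, blood, and fibroblast and endothelial markers for cells that do not belong in the culture. Of their 500 symbols, 439 were tested. Lists were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusting over the 21 lists.

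The rule for named genes took 7 fixed genes (CALR, CANX, CTNNB1, HIF1A, MYC, CCND1 and AXIN2), the 8 largest differences in each direction past the adjusted threshold with non-overlapping groups and a mean log2 CPM of at least 1, and the leading members of each list past that threshold. The last 2 parts named 0 genes. The other genes in the text were therefore chosen after their values were seen, by the same rule at an unadjusted p under 0.05, or because they passed the adjusted threshold after the GC correction, or as members of a list with their values stated. The single values of 2 genes are not reported here.

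The alternatives were DESeq2's median-ratio factors in the edgeR test, library size alone, DESeq2 1.42.0 (10 genes without an adjusted p), limma-voom, no low-count filter, a CPM of at least 1 in all 6 libraries, leaving out each library, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 1 in 3 libraries, log2(FPKM + 1) without that filter, an adjusted threshold of 0.01, and edgeR's test against a 1.5-fold change. After the data were seen, a GC correction was added, alone and with each library left out, and limma-voom with sample quality weights. The GC correction fitted a loess curve (span 0.3) of each library's log2 CPM deviation on transcript GC content for the 98.9% of tested genes with a value, and passed it to edgeR as an offset. A first version, which also let the correction shift each library's median, called 10 genes; the version reported here was made after that result was seen, holds the median and called 7, all of them among the 10.

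The same code was tested on simulated counts drawn from these libraries' means and depths. Genes were drawn independently of each other, with 1 spread per gene that both groups shared. At 16394 genes, the test recovered 30 of 100 genes changed 2-fold and 89 of 100 changed 4-fold and called 5 unchanged genes, and it called the 1 list shifted by 0.5 and 0 others. With simulated GC trends, the correction recovered 37 of 99 and 93 of 99 such genes among 16215, with 12 unchanged genes called. The simulation held neither correlation between list members nor a wider spread among knockdown libraries. It therefore checks the code and cannot vouch for the list or gene calls in the real data.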

Results

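Calreticulin, encoded by CALR, is a calcium-binding chaperone of the endoplasmic reticulum (ER). The series title places it under HIF-1 control and upstream of Wnt/beta-catenin signalling in breast tumours, and the RNA sequencing asked which transcripts of MDA-MB-231 cells differ once CALR is knocked down. MDA-MB-231 is a mesenchymal, hormone receptor-negative breast cancer line. Total counts were 37295097, 38336250 and 42425310 in CALR knockdown replicates 1 to 3, and 37034052, 34639090 and 40732131 in control replicates 1 to 3.

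CALR was lower in all 3 knockdown libraries, by very different amounts. The gene lies on chromosome 19 at 12938578 to 12944489 of GRCh38 (plus strand, ENSG00000179218.13). It had 17272, 2674 and 4102 counts in the knockdown libraries, and 45846, 35662 and 40382 in the controls. As normalised counts these were 493, 66.4 and 110 CPM against 1213, 979 and 926 CPM. The remaining CALR was therefore 47.5% of the control mean in knockdown replicate 1, 6.39% in replicate 2 and 10.6% in replicate 3. The fitted log2 fold change was −2.22 ± 0.64 (SE, 3 against 3), with an unadjusted p of 0.0075 and an adjusted p of 0.209 in edgeR's quasi-likelihood test. The exact two-sided permutation test of log2 CPM gave p = 0.1, the smallest this design allows. Without knockdown replicate 1 the log2 fold change was −3.55, with an adjusted p of 0.086 from edgeR.

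**Figure D1:**
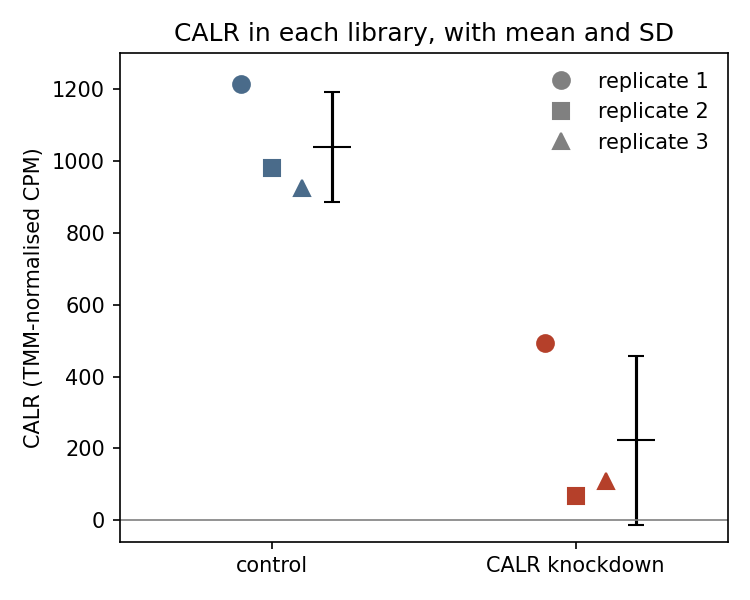
CALR in each library as TMM-normalised CPM, with symbols for replicates 1 to 3 and a bar for the mean and SD of each group (n = 3). All 3 knockdown libraries (66.4 to 493 CPM) lie below all 3 controls (926 to 1213 CPM), and replicate 1 holds the most remaining CALR.

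Across the transcriptome, the genes that differed most steadily between the groups were GFPT2, APCDD1L and ADAMTS6. GFPT2, an enzyme of the hexosamine pathway, was at 166 ± 21.6 CPM in knockdown and 64.6 ± 5.78 in control libraries (SD, n = 3), a log2 fold change of 1.36 ± 0.17 (SE). APCDD1L, a homologue of the Wnt inhibitor APCDD1, was at 20.5 ± 4.03 against 4.71 ± 0.871 CPM (log2 fold change 2.12 ± 0.25). ADAMTS6, a secreted metalloprotease, was at 6.37 ± 0.291 against 21.4 ± 1.83 CPM (log2 fold change −1.75 ± 0.19). No single gene passed the adjusted threshold, however, and the smallest adjusted p from edgeR was 0.115. At an unadjusted p under 0.05, edgeR gave 2546 of 16394 genes, 1340 higher and 1206 lower in knockdown, where chance gives 820. Both groups were fully apart for 1849 genes higher and 1835 lower in knockdown, 22.5% of those tested against 10% by chance. The adjusted count was also 0 with limma-voom and was 530 with DESeq2 (290 higher, 240 lower). It reached 2604 (1303 higher, 1301 lower) without knockdown replicate 2 and 138 (21 higher, 117 lower) without knockdown replicate 3.

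After each library's trend with GC content was removed, an alternative added once the data had been seen, 7 genes passed edgeR's adjusted threshold, each at an adjusted p of 0.043. The log2 fold changes in that fit were 2.12 for APCDD1L, 1.31 for GFPT2, 1.27 for GBP1, 1.21 for C8orf82, 1.12 for ME1, 1.01 for SBF1 and −1.60 for ADAMTS6. GBP1, one of a family of similar genes whose reads may be shared, is an interferon-inducible GTPase and ME1 the cytosolic malic enzyme, which supplies NADPH. All 3 knockdown libraries lay on one side of all 3 controls for each of the 7. Leaving out any one control library ended all 7 calls, and 4 were kept without knockdown replicate 1.

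Among genes with groups fully apart, an unadjusted p under 0.05 and a mean log2 CPM of at least 1, those furthest above the controls included the tetraspanin CD82, at 181 ± 46.7 against 45.6 ± 16.0 CPM (log2 fold change 1.98 ± 0.29). C15orf48, which encodes a small mitochondrial protein, was at 404 ± 152 against 106 ± 16.3 CPM, with 20.9% of its exon bases shared with other annotated transcripts on the same strand. The protease ADAM8 had a log2 fold change of 1.70 ± 0.37, the matrix gene OLFML2B 1.85 ± 0.43 and the aldo-keto reductase AKR1B10, which has close paralogs, 2.14 ± 0.49. MYH15, at 2.18 ± 0.72, owed much of its difference to replicate 2, whose log2 CPM was 3.43 above the control mean against 0.86 and 0.73 in replicates 1 and 3. Furthest below the controls, CALR apart, were BST2 (−2.54 ± 1.06, and −5.16 to −1.75 with 1 library left out), at 3.89 CPM in knockdown replicate 3 against 4.31 in control replicate 3, the protocadherin PCDH1 (−2.19 ± 0.48), the lactate transporter SLC16A1 (−2.13 ± 0.64), PELI2 (−2.09 ± 0.42), TC2N (−2.01 ± 0.40), LSR (−1.92 ± 0.51), a component of tricellular junctions, and DMKN (−1.84 ± 0.59). Without knockdown replicate 3, SLC16A1 was at −3.31 and DMKN at −2.92. Adjusted p-values from edgeR for these genes lay between 0.145 and 0.304.

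**Figure D2:**
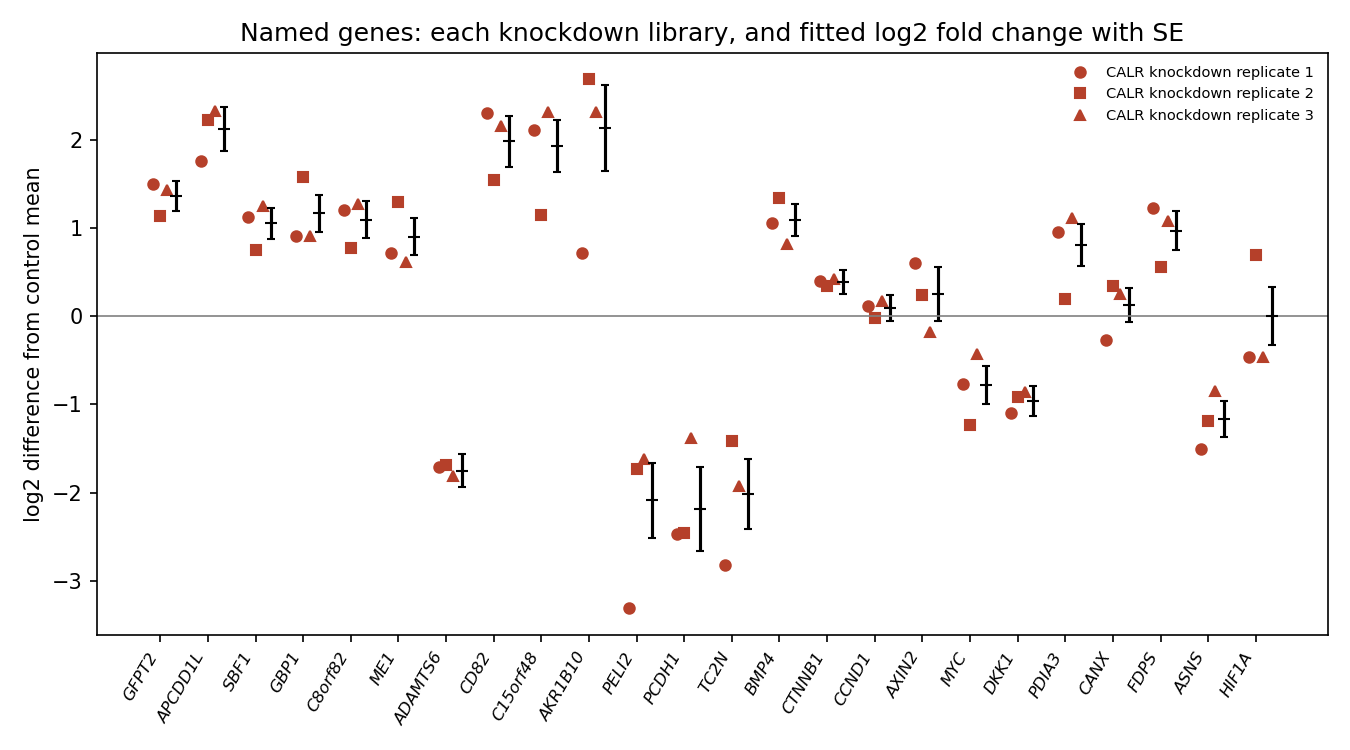
Log2 difference of each knockdown library from the mean of the 3 controls (symbols) for 24 of the genes given here, with edgeR's log2 fold change and its SE (bars). ADAMTS6 sits near −1.75 in all 3 libraries, whereas HIF1A lies above the control mean in replicate 2 and below it in replicates 1 and 3.

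The Wnt genes went in both directions. CTNNB1, which encodes beta-catenin, was at 317 ± 8.78 CPM in knockdown and 242 ± 10.9 in control libraries, higher in all 3 (log2 fold change 0.39 ± 0.14). MYC was lower in all 3, at 173 ± 46.9 against 296 ± 28.5 CPM (−0.78 ± 0.22). The Wnt antagonist DKK1 was lower in all 3 (−0.96 ± 0.17) and the growth factor BMP4 higher in all 3 (1.09 ± 0.18). CCND1 (0.09 ± 0.14) and AXIN2 (0.25 ± 0.30, and 0.04 to 0.45 with 1 library left out) differed by less than the spread between replicates, and AXIN2 shares 25.2% of its exon bases with another transcript on the same strand. Of 27 listed Wnt/beta-catenin target genes 20 were tested, without LGR5, NKD1, NKD2, NOTUM, ASCL2, APCDD1 and MMP7. Of the 20 tested, 0 passed the adjusted threshold over all genes. At an unadjusted p under 0.05, 3 were higher and 2 lower. Adjusted over the list alone, BMP4 and PLAUR were higher and DKK1 and MYC lower. The list's median log2 fold change was 0.08, which turned to −0.05 with library size alone and to between −0.04 and −0.03 on the FPKM scale, and camera's adjusted p was 0.411. Fry in limma, which does not compare a list with other genes, gave an adjusted p of 0.0032 for change in either direction and 0.836 for change in one direction. Among 36 Wnt receptors, ligands and transducers the median was −0.06 (camera adjusted p = 0.891). At an unadjusted p under 0.05, 4 of them were higher and 3 lower. These included the receptor FZD1 (1.18 ± 0.38), the co-receptor LRP5 (0.76 ± 0.29) and the repressor TCF7L1 (−1.24 ± 0.41). Without knockdown replicate 1, FZD1 was at 0.64 and LRP5 at 0.48.

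HIF1A itself was at 218 ± 111 CPM in knockdown and 218 ± 55.8 in control libraries. Of 33 tested hypoxia and HIF-1 target genes, 8 were higher and 1 lower at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone or over all genes. The glucose transporter SLC2A1 (0.79 ± 0.25) and the glycolytic genes GAPDH (0.79 ± 0.23) and ALDOA (0.77 ± 0.22) were higher in all 3 knockdown libraries, and the collagen-modifying enzyme PLOD2 was lower in all 3 (−0.94 ± 0.26). After the GC correction SLC2A1 and GAPDH were at 0.68, ALDOA at 0.65 and PLOD2 at −0.57 ± 0.23. ALDOA shares 42.3% of its exon bases with another transcript on the same strand, and GAPDH has many processed pseudogenes, so both counts are uncertain. The list's median was 0.33 (camera adjusted p = 0.070, or 0.944 with an estimated correlation). It rested on replicate 1, whose own median was 0.80 above the control mean against −0.20 and 0.20 in replicates 2 and 3, and without that library the median was −0.03. Of 20 listed stem cell genes 14 were tested, without NANOG, POU5F1, ALDH1A1, PROM1, LIN28B and NODAL. SOX2 was tested near the floor, at means of 0.210 CPM in knockdown and 0.208 in control libraries. The median of the 14 was 0.23 (camera adjusted p = 0.403), with 1 member higher and 2 lower at an unadjusted p under 0.05. ITGB3, which shares 51.6% of its exon bases with another transcript on the same strand, was higher (1.32 ± 0.41), and the pluripotency factors KLF4 (−0.84 ± 0.24) and SALL4 (−0.96 ± 0.35) were lower in all 3 libraries. Mean expression was low for ITGB3, at 1.60 CPM in knockdown and 0.642 in control libraries, and for SALL4, at 0.727 and 1.42.

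Of 29 tested ER chaperones and folding enzymes, which work in the same compartment as calreticulin, 24 had a positive log2 fold change, with a median of 0.31 (camera adjusted p = 0.0049, or 0.870 with an estimated correlation). The disulphide isomerase PDIA3, which works together with calreticulin, had a log2 fold change of 0.81 ± 0.23, PDIA4 0.79 ± 0.24, CRELD2 0.88 ± 0.28 and the glucosidase subunit GANAB 0.61 ± 0.22. CANX, which encodes the membrane-bound homologue calnexin, was at 940 ± 201 against 860 ± 48.9 CPM (0.13 ± 0.19). Without knockdown replicate 3 CRELD2 was at 0.57, and CANX was at 0.01 to 0.30 with 1 library left out. The counts at an unadjusted p under 0.05 were 7 higher and 1 lower, and 0 members passed when adjusted over the list alone. Replicates 1 and 3 had medians of 0.35 and 0.54 above the control mean, replicate 2 only 0.02, and without replicate 3 camera's adjusted p was 0.096. Of 30 calcium handling genes, 4 were higher at an unadjusted p under 0.05, with a median of 0.06 (camera adjusted p = 0.638) that was −0.08 with library size alone and between −0.07 and −0.04 on the FPKM scale. ATP2A2, the ER calcium pump, had a log2 fold change of 0.54 ± 0.15 and CALM3, a calmodulin gene, 0.61 ± 0.19.

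Most ATF4/CHOP stress genes were lower. Of 24 tested members, 21 had a negative log2 fold change, and the median was −0.51 (camera adjusted p = 3.4e-05, or 0.870 with an estimated correlation). Adjusted over the list alone, 5 were lower and 0 higher. Those 5 were asparagine synthetase ASNS (−1.17 ± 0.21), the serine synthesis gene PSAT1 (−0.90 ± 0.19), MTHFD2 of mitochondrial folate metabolism (−0.68 ± 0.18), the transcription factor CEBPG (−0.72 ± 0.15) and CHAC1 (−1.35 ± 0.38). ASNS shares 44.6% of its exon bases with another transcript on the same strand. After the GC correction ASNS was at −1.03 ± 0.23 and CEBPG at −0.52 ± 0.18. The list's median was −0.91 and −0.95 in replicates 1 and 2 and −0.09 in replicate 3, where control replicate 3 had −0.12, and the fitted median was −0.85 without knockdown replicate 3. Immediate early genes were lower too, with a median of −0.70 over 16 members (camera adjusted p = 0.0058, or 0.870 with an estimated correlation). At an unadjusted p under 0.05, 5 of them, among them BTG2 (−2.45 ± 0.66) and NR4A1 (−1.25 ± 0.40), were lower and 1 was higher, 0 passed over the list alone, and without replicate 2 camera's adjusted p was 0.184. Their library medians were −0.86, −1.17 and −0.12 in knockdown replicates 1 to 3 and −0.40, 0.30 and 0.11 in the controls, and the fitted median was −1.14 to −0.48 with 1 library left out. BTG2 was at −3.88 without knockdown replicate 3. It was low in both groups, at means of 0.222 CPM in knockdown and 1.23 in control libraries, so its fold change is uncertain.

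Most cholesterol synthesis genes were higher, with a median of 0.51 over 24 members, 22 of them positive (camera adjusted p = 3.4e-05, or 0.870 with an estimated correlation). Adjusted over the list alone, 9 were higher and 0 lower, among them FDPS (0.97 ± 0.22) and FDFT1 (0.69 ± 0.19). MHC class I antigen presentation genes had a median of 0.47 over 19 members (camera adjusted p = 0.0049, or 0.870 with an estimated correlation), and 4 were higher over the list alone, namely the transactivator NLRC5 (0.96 ± 0.21), the proteasome activator PSME1 (0.65 ± 0.15), TAPBP (0.53 ± 0.16) and B2M (0.66 ± 0.20). In both lists replicate 2 stayed near the controls, with medians of 0.08 and −0.09, and without it the fitted median of the MHC class I list was 0.71.

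Integrin and matrix genes had a median of 0.34 over 24 members (camera adjusted p = 0.014, or 0.870 with an estimated correlation), with COL6A3 (1.48 ± 0.31) and COL6A1 (0.77 ± 0.20) higher over the list alone. At an unadjusted p under 0.05, 6 members were higher and 2 lower, the latter NID2 (−2.89 ± 0.82) and COL1A1 (−0.91 ± 0.30). NID2 was low in both groups, at means of 0.143 CPM in knockdown and 1.08 in control libraries. Control replicate 1 had a list median of 0.38, above the 0.11 and 0.27 of knockdown replicates 2 and 3, and the fitted median was 0.21 to 0.62 with 1 library left out. G2/M genes had a median of 0.42 over 24 members (camera adjusted p = 0.0061, or 0.944 with an estimated correlation), with 7 higher and 0 lower at an unadjusted p under 0.05, among them CDC20 (0.65 ± 0.21) and KIF20A (0.84 ± 0.29), and 0 over the list alone. Its library medians were 0.70, 0.46 and −0.31 in knockdown replicates 1 to 3 and 0.44, −0.21 and −0.19 in the controls, and the fitted median was 0.19 to 0.63 with 1 library left out. The camera calls of both lists were lost without knockdown replicate 1 and without control replicate 2, at adjusted p-values of 0.20 and 0.12 for integrins and matrix and of 0.23 and 0.091 for G2/M. That of G2/M was also lost without knockdown replicate 2 (0.19). S phase genes did not pass (median 0.24, camera adjusted p = 0.148) but did without knockdown replicate 2 (0.030) or 3 (0.018), and without replicate 1 their median was 0.04. MCM5 was at 0.53 ± 0.22, and without replicate 1 MCM5 was at 0.28 and KIF20A at 0.53.

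The mesenchymal list had a median of 0.16 (camera adjusted p = 0.891) that was between −0.15 and −0.05 on the FPKM scale and with library size alone. With 1 library left out it was −0.13 to 0.60. Of its 22 tested members, 12 had a positive and 10 a negative log2 fold change. The secreted protease PLAU (1.36 ± 0.27), the membrane metalloprotease MMP14 (1.21 ± 0.25) and vimentin VIM (0.65 ± 0.16) were higher over the list alone, and 0 members were lower. Negative values included the transcription factors TWIST1 (−2.06 ± 1.09), SNAI1 (−0.76 ± 0.49), SNAI2 (−0.49 ± 0.30), ZEB2 (−0.33 ± 0.19) and ZEB1 (−0.20 ± 0.43), and the cadherin CDH2 (−1.21 ± 0.60). TWIST1 and CDH2 were low in both groups. The epithelial list (median −0.05, camera adjusted p = 0.704) held the desmosome gene DSP (−1.12 ± 0.20) and the keratin KRT7 (−0.86 ± 0.22), lower over the list alone, and the tight-junction gene CLDN4, higher at 72.4 ± 13.1 against 36.2 ± 7.97 CPM. Interferon-stimulated genes had a median of 0.07 (camera adjusted p = 0.985), which was −0.06 with library size alone and −0.10 to 0.15 with 1 library left out. OAS3 was at 0.59 ± 0.16 and IFIT2 at −0.84 ± 0.26. NF-kB cytokine genes had a median of 0.34 (camera adjusted p = 0.839), with BIRC3 at −0.82 ± 0.26 (−0.59 ± 0.15 after the GC correction) and NFKBIA at 0.61 ± 0.24 (0.52 ± 0.20). Their library medians were −0.04, −0.46 and 0.97 in knockdown replicates 1 to 3, and without replicate 3 the median was −0.17 and passed (camera adjusted p = 0.035), and NFKBIA was at 0.29.

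Among the lists of other cell types, luminal breast markers had a median of 0.16 (camera adjusted p = 0.403), blood markers −0.02 (0.860) and fibroblast and endothelial markers −0.13 (0.894). With 1 library left out, the blood median was −0.089 to 0.091 and the fibroblast and endothelial median −0.30 to 0.34. The luminal list was the 1 list of 21 whose library medians were all higher in knockdown (0.25 to 0.37) than in control libraries, although the fitted median was −0.01 on the FPKM scale without a filter and 0.05 to 0.48 with 1 library left out, with MLPH at 0.60 ± 0.19 and KRT15 at 0.76 ± 0.28. Of the 4 tested blood markers, the actin-bundling gene LCP1 was at 427 ± 196 CPM in knockdown and 202 ± 14.2 in control libraries. PECAM1 (1.19 ± 0.44) and DCN (−2.23 ± 0.86) were low in every library, at group means of 0.394 to 2.57 CPM. The log2 fold change of LCP1 was 1.08 ± 0.30, and without knockdown replicate 1 it was 0.68 for LCP1 and 0.66 for PECAM1. Mitochondrially encoded mRNAs had a median of −0.04 (camera adjusted p = 0.985). For the blood, fibroblast and mitochondrial lists the median and camera's direction differed in sign. Protein-coding genes took 97.5 ± 0.32% of counts in knockdown and 96.4 ± 0.16% in control libraries, and the mitochondrial rRNA MT-RNR2 took 0.624 ± 0.33% and 1.38 ± 0.149%, both at an exact two-sided permutation p of 0.1.

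Of the 21 lists, 7 passed camera's adjusted threshold with the preset correlation, 5 higher and 2 lower, and 0 passed with an estimated correlation (smallest unadjusted p 0.173) or with fry's test of one direction (smallest adjusted p 0.383). In those 7 lists the estimated correlation between members ran from 0.24 (integrins and matrix) to 0.77 (G2/M). It was 0.38 for ATF4/CHOP and 0.48 for cholesterol synthesis genes. The preset of 0.01 does not allow for correlations of that size. Fry's test of change in either direction passed for 7 lists, led by the Wnt/beta-catenin targets. The others were stem cell, epithelial, integrin and matrix, luminal, fibroblast and endothelial, and mesenchymal genes, at adjusted p-values from fry of 0.021 to 0.044. Since lists unrelated to Wnt signalling also passed, this test was not specific to Wnt genes. The luminal and the fibroblast and endothelial lists were chosen for cells that do not belong in the culture. However, the luminal gene MLPH was at a mean of 86.0 CPM in control libraries, so the luminal list does not measure such cells alone. In 0 of camera's 7 lists did the 3 knockdown medians lie fully outside the 3 control medians.

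**Figure D3:**
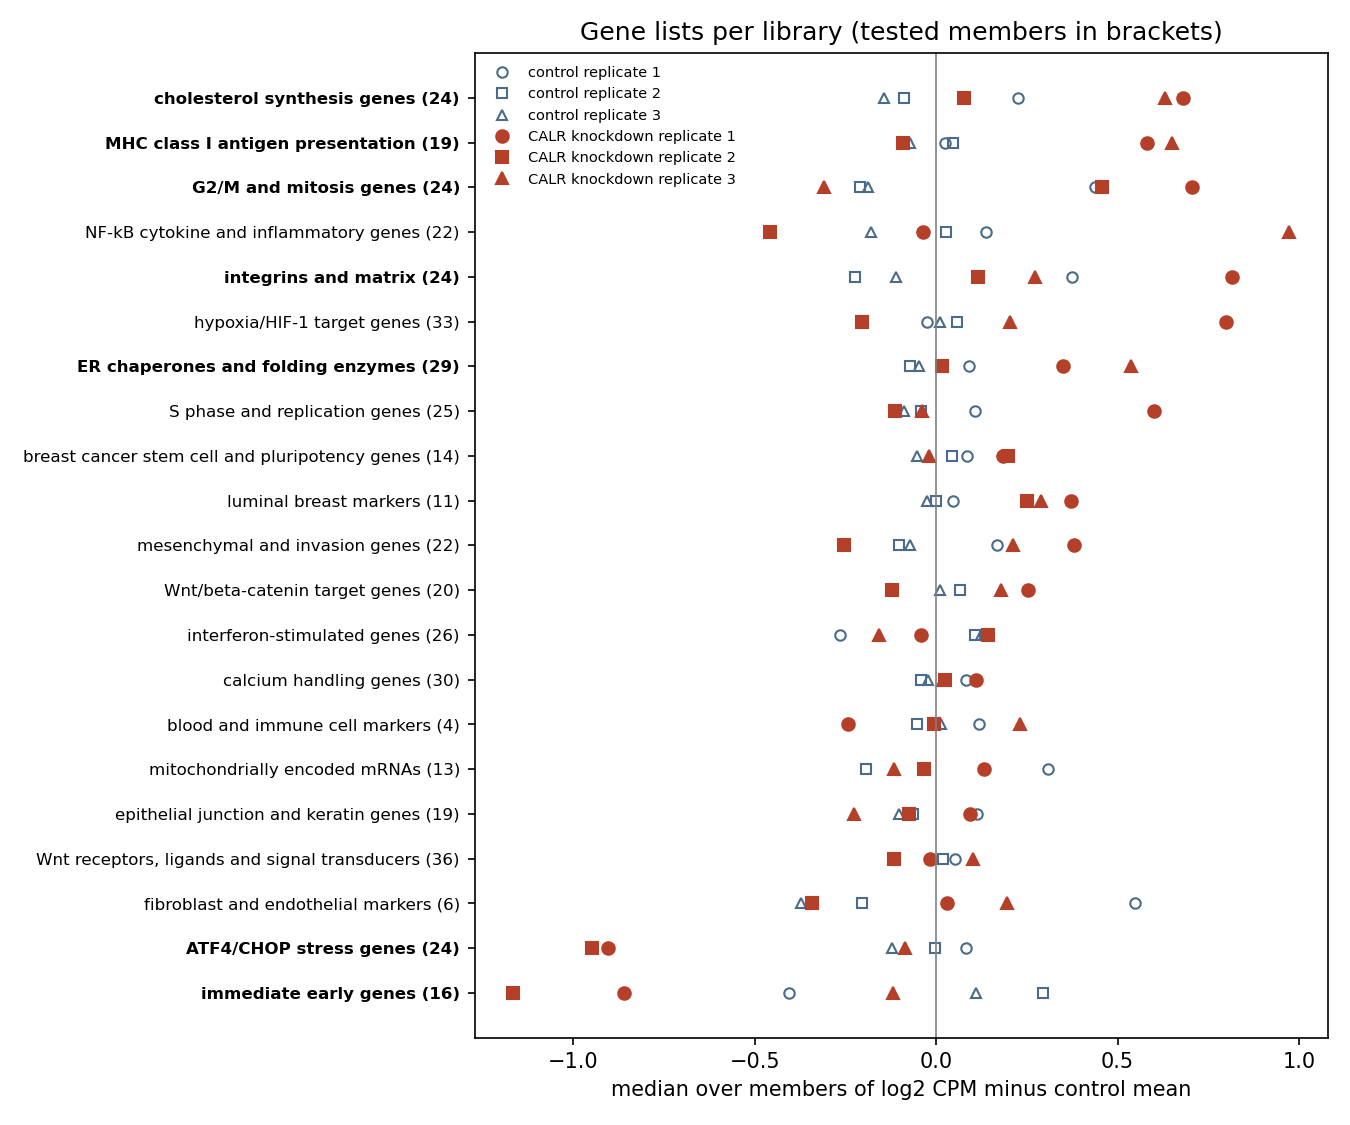
Median over the tested members of each gene list of log2 CPM minus the mean of the controls, for each knockdown library (filled) and control library (open). List names in bold passed camera's adjusted threshold with the preset correlation. Cholesterol synthesis genes lie at 0.68, 0.08 and 0.63 in knockdown replicates 1 to 3, and ATF4/CHOP genes at −0.91, −0.95 and −0.09.

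The knockdown libraries differed more from each other than the controls did. The median variance of log2 CPM was 0.137 among knockdown and 0.028 among control libraries, and 82.6% of genes varied more in knockdown. Their deviations also followed GC content. Across genes, Spearman's rho between a library's deviation and transcript GC content was 0.29, −0.44 and 0.53 for knockdown replicates 1 to 3 and −0.22, −0.08 and −0.37 for the controls, and rho between log2 fold change and GC content was 0.30. Genes are not independent replicates, so no p is attached. The first principal component held 42.2% of the variance and set the 3 knockdown libraries apart from the 3 controls. On it replicate 1, with the most CALR left, lay furthest from the controls, at −63.7 against −25.6 and −17.3 in replicates 2 and 3. The controls lay at 31.7 to 37.6, so the distance did not follow the loss of CALR. The second component held 31.4% and lay mainly between knockdown replicates 2 and 3.

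**Figure D4:**
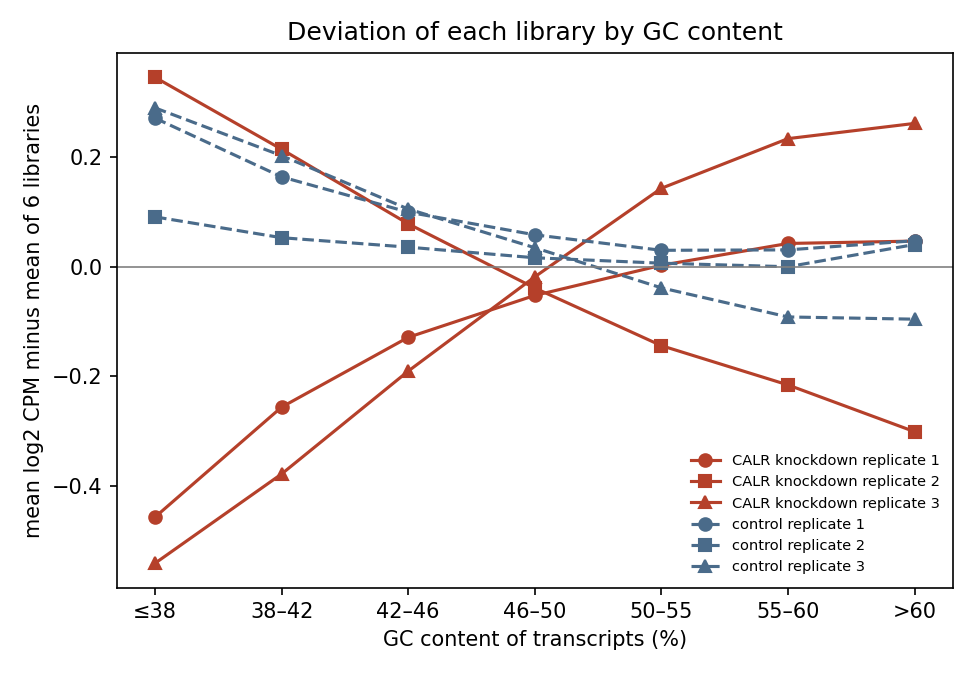
Mean deviation of log2 CPM from the mean of the 6 libraries for genes grouped by transcript GC content. Below 38% GC the mean was −0.46 and −0.54 in knockdown replicates 1 and 3 and 0.35 in replicate 2, and the 3 libraries swapped sides above 50%.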

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

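The GC correction and the sample quality weights were chosen after seeing the data; the other settings were fixed before. The count of genes past the adjusted threshold, 0 with edgeR, was 530 with DESeq2 (290 higher, 240 lower, 263 at least 2-fold) and 988 without the low-count filter (431 higher, 557 lower, 630 at least 2-fold), where 3888 genes had an unadjusted p under 0.05. In that unfiltered fit edgeR drew each gene's spread fully to the common trend, against a prior weight of 4.85 degrees of freedom with the filter. On the FPKM scale without a filter limma gave 5 genes (3 higher, 2 lower). The GC correction gave 7 (6 higher, 1 lower, all 7 at least 2-fold), and 12 (7 higher, 5 lower), 861 (612 higher, 249 lower) and 350 (107 higher, 243 lower) when knockdown replicate 1, 2 or 3 was also left out. With quality weights limma-voom gave 2236 (1125 higher, 1111 lower, 871 at least 2-fold) and 5506 at an unadjusted p under 0.05. Leaving out 1 library gave between 0 and 2604 genes (0 to 1303 higher, 0 to 1301 lower, 0 to 769 at least 2-fold, 1206 to 5978 unadjusted), with the most without knockdown replicate 2. All 7 GC-corrected genes were kept without knockdown replicate 2 or 3. Of the DESeq2 calls, 443 were also called without knockdown replicate 2 and 61 without replicate 3. Median-ratio factors, library size alone, limma-voom, the stricter filter, the filtered FPKM fits, the 0.01 threshold and the test against a 1.5-fold change each gave 0 genes. The causes of these differences were not tested beyond the prior weight.

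Same-numbered libraries of the groups had deviation correlations of 0.20, −0.12 and −0.22, so the replicate numbers were not taken to pair them. With the replicate number as a block edgeR called 0 genes, the CALR log2 fold change was −2.77 and 8 lists passed. Under that block the hypoxia list passed the threshold, with a median of 0.20. HIF1A (−0.085) and the medians of mesenchymal (−0.13) and interferon-stimulated genes (−0.0027) had the opposite sign to the fit without the block.

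CALR stayed lower in every setting run, from −3.64 to −1.78, both reached by leaving out a knockdown library (−3.55 to −1.78 without the GC correction). It passed the adjusted threshold without the low-count filter (−2.19, edgeR adjusted p = 1.4e-19), with quality weights (−1.94, limma adjusted p = 0.021) and with the GC correction without knockdown replicate 1 (−3.64, edgeR adjusted p = 0.0097), and its adjusted p was between 0.054 and 0.560 when 1 library was left out and nothing else differed. Apart from CALR, 72 named genes had 1259 alternative values, of which 1240 kept their direction and 231 passed the threshold. The 19 that turned were of HIF1A, CCND1 and CANX, which were fixed beforehand. Most of the 72 were chosen by their p-values in these same libraries, so that they kept their direction is no independent support. HIF1A was −0.083 with library size alone, −0.078 with limma-voom, −0.028 with the stricter filter, −0.20 in each FPKM fit, −0.16 with quality weights and −0.49 to 0.24 with 1 library left out. CCND1 was −0.047 with library size alone and −0.035 in each FPKM fit, and CANX was −0.019 with FPKM + 1, filtered or not, −0.020 with FPKM + 0.1 and −0.031 with quality weights.

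The number of lists past the threshold was 5 to 8 with 1 library left out, and 0 with an estimated correlation and with fry, which left the medians as they were (ER chaperones 0.31, ATF4/CHOP −0.51, cholesterol synthesis 0.51). With 1 library left out these medians were 0.22 to 0.39, −0.85 to −0.36 and 0.38 to 0.63. The hypoxia list passed with library size alone (0.16), DESeq2 (0.34), no filter (0.35), the filtered FPKM fits (0.069 with a pseudocount of 1 and 0.068 with 0.1) and quality weights (0.41), and its median was −0.028 to 0.54 with 1 library left out, passing without knockdown replicate 2 and without control replicate 2 or 3. S phase genes passed with quality weights (0.40), without knockdown replicate 2 (0.38) and without replicate 3 (0.34), and had 0.045 without replicate 1. Library size alone moved the median of all genes to −0.13, and log2(FPKM + 0.1) to −0.11. With library size alone, Wnt targets had −0.054, calcium handling −0.077, mesenchymal −0.054 and interferon-stimulated genes −0.056. In the FPKM fits with a pseudocount of 1, of 0.1 and of 1 without a filter, in that order, Wnt targets had −0.035, −0.042 and −0.027, calcium handling −0.065, −0.072 and −0.045, mesenchymal −0.15 in each, and interferon-stimulated genes −0.063, −0.12 and −0.063. Without the FPKM filter, luminal markers had −0.0072 and fibroblast and endothelial markers 0.0048. With limma-voom, mesenchymal genes had −0.14 and interferon-stimulated genes −0.0011. Fibroblast and endothelial markers were 0.46 without the low-count filter, 0.36 with the stricter filter and 0.30 with quality weights; blood markers were 0.018 with the stricter filter, and epithelial genes 0.0085 without the filter. Mitochondrial mRNAs were 0.040 with the GC correction and 0.14 with quality weights, which gave −0.11 for interferon-stimulated genes. With 1 library left out, medians were −0.17 to 0.56 for NF-kB cytokines, −0.13 to 0.60 for mesenchymal, −0.10 to 0.15 for interferon-stimulated, −0.089 to 0.091 for blood, −0.30 to 0.34 for fibroblast and endothelial and −0.14 to 0.11 for mitochondrial genes, 0.024 to 0.20 for Wnt targets, −0.083 to −0.024 for Wnt receptors, ligands and transducers, 0.11 to 0.25 for stem cell genes, 0.38 to 0.71 for MHC class I, 0.017 to 0.087 for calcium handling, −0.18 to −0.0012 for epithelial genes and 0.051 to 0.48 for luminal markers. The causes of these turns were not tested.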

Other observations

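The tests of the spread between knockdown libraries were chosen after their results were seen, and the GC correction, the NRF2 list and the genes named per library after the data had been looked at. The other tests that use the GC correction were written down before its first version was run, and the version reported holds each library's median, a change made after the first version's results were seen.

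Some inflammatory and matrix-remodelling genes differed widely between the knockdown libraries. Relative to the control mean on the log2 scale, the acute-phase genes SAA1 and C3 were at −4.38 and −3.61 in replicate 2, at 1.66 and 2.51 in replicate 1 and at 1.37 and 2.45 in replicate 3. IL1B had values of 2.55, −1.49 and 2.56 in replicates 1 to 3, and IL6 0.67, −1.75 and 2.29. The chemokine genes CXCL8 (2.09) and CXCL2 (2.20) lay above the control mean in replicate 3, at −1.13 and −0.21 in replicate 1 and at −0.75 and −0.92 in replicate 2. SERPINB2 and the collagenase MMP1 were at −3.94 and −3.25 in replicate 1 and at −3.83 and −3.05 in replicate 2, but at 0.88 and 0.77 in replicate 3. KLF9, a glucocorticoid-responsive transcription factor gene, was at −1.14, −3.52 and −1.04. Control libraries spread too, from −0.80 to 1.30 for SAA1 and from −1.13 to 1.99 for C3 but only from −0.04 to 0.03 for MMP1. These genes were picked for differing between libraries, and no test was made of them as a group.

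A further pattern was the height of genes that the stress-responsive factor NRF2 activates. HMOX1 (log2 fold change 1.64 ± 0.29), AKR1C3 (1.37 ± 0.22), PIR (1.37 ± 0.25), NQO1 (1.18 ± 0.29) and ME1 (0.90 ± 0.21) were higher in all 3 knockdown libraries, AKR1C3 with near-identical paralogs that may share its reads. GCLM (1.15 ± 0.46) and FTL (0.99 ± 0.33) did not have groups fully apart. Because these and AKR1B10 had been seen first, 20 other NRF2 targets were set apart as a test, of which 1, SLC7A11, is also on the ATF4/CHOP list. The 20 include AKR1C1 and AKR1C2, paralogs of AKR1C3, and were measured in the same 6 libraries, so the test is not independent. The median of the 20 was 0.42 ± 0.12 before and after GC correction, so the GC trend is argued against as the whole cause. The SE is over members and treats them as independent. Camera gave p = 0.0010 with the preset and 0.165 with an estimated correlation, and 7 of the 20 were higher and 0 lower at an unadjusted p under 0.05. Higher NRF2 target expression in each knockdown library may be a response to less CALR, but the lowest library median was 0.039 ± 0.196 in replicate 1, against 0.42 and 0.59 in replicates 2 and 3, so this stays open.

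The 3 knockdown libraries differed from each other more than the controls, with a variance ratio of 4.89. Removing each library's GC trend left the ratio at 3.60, so GC content is a candidate cause of part of it and not of the whole. If the amount of remaining CALR set the libraries apart, replicates 2 and 3, with the least CALR, should have been the closest pair. Their root-mean-square difference was 1.18 times that of the more distant of the other pairs, and 1.11 times after the GC correction. Replicates 2 and 3 were thus the most distant pair both times, the opposite of that prediction. Remaining CALR alone therefore did not order the 3 pairs. A part played by CALR stays open, since pairs of controls also differed unequally. Their root-mean-square differences were 0.47, 0.46 and 0.31, and 0.46, 0.45 and 0.28 after the GC correction. Different shRNAs, infections or culture states also stay open, as the labels do not give them and they were not tested.

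The list medians for ATF4/CHOP, cholesterol synthesis and ER chaperone genes may in principle follow GC content. After the GC correction they were −0.56 ± 0.075, 0.53 ± 0.065 and 0.38 ± 0.055 (SE over members), against −0.51 ± 0.140, 0.51 ± 0.104 and 0.31 ± 0.082 before, so the trend is not the whole cause of any of the 3. A response to CALR knockdown and a difference between cultures both stay open, since replicate 3 for ATF4/CHOP genes and replicate 2 for the other lists lay near the controls.

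The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. With edgeR, the adjusted count was 0 in the real split, where 2546 genes had an unadjusted p under 0.05 and DESeq2 called 530, and at most 0 in the others, so all 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 2546 genes and the highest other 2153, so 1 split gave as many. After the GC correction the real split gave 7 and the highest other 0, again 1 split. For the lists, the real split gave 7 past camera's threshold and the highest other 12, with 5 splits giving as many.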
